A study of Arabidopsis thaliana with 12 samples.

How the data were processed

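RNA was measured in 12 libraries of wild type Columbia Arabidopsis thaliana seedlings, 3 libraries in each of 4 groups. Per the labels, seedlings grew for 7 days at 21°C in 8 h of light and 16 h of dark. They were then moved to 27°C or left at 21°C, with or without mannitol, 1 h after lights on, and were collected 12 h later. Mannitol is a sugar alcohol that lowers the water potential of the medium and serves as a drought-like osmotic treatment; its dose is not given in the sources used here. Total RNA was extracted with a column kit, and libraries were made with the NEBNext Ultra RNA kit, for which the labels state no strand. The replicates carry the numbers 1 to 3, and the labels do not say whether they were grown, harvested or extracted separately, so every p-value measures only the spread between these 12 samples.

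The authors deposited a single table of TPM values, in which a gene's reads are divided by a gene length and scaled to a sum of 1000000 in each library. Its column names call the values counts, but each of the 12 columns sums to 1000000 and the values are not whole numbers. The labels name fastp 0.20.1, HISAT2, DESeq2 1.26.0 and the TAIR10 genome without giving their order or role. The counting tool, the gene lengths and any filter are not given in the sources used here. The table holds 27655 genes with identifiers of the Araport11 gene models. Of these identifiers, 27445 matched the TAIR10.1 reference, from which symbols were taken; the other 210 are 88 chloroplast and 122 mitochondrial genes. No coordinates were used.

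Depth was estimated from the values themselves. A common step size that turns a gene's TPM into whole reads within a tolerance of 0.01 was found for 21755 of the 21760 genes above 0 in at least 6 libraries. The recovered reads came to between 13471976 and 14565660 per library. They are a reconstruction, so they served only for depth and for 1 alternative test (voom), chosen after seeing the data.

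Values were transformed to log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 libraries were tested, 20005 in all, and 7650 were left out. All tests used limma 3.58.1 in R 4.3.3, with 4 group means, no covariate, a mean-variance trend in the empirical Bayes step and two-sided p-values. Benjamini-Hochberg adjusted p-values below 0.05 were called over the tested genes of each contrast. There were 5 contrasts: 27°C against 21°C, mannitol at 21°C, mannitol at 27°C, 27°C against 21°C with mannitol, and the interaction, which is the warm response with mannitol minus the warm response without it. The interaction equals the mannitol effect at 27°C minus that at 21°C. A log2 difference is given with the standard error (SE) of the fit, a TPM with the standard deviation (SD) of 3 libraries. Because 1 is added to each TPM, the log2 difference of a gene near 0 TPM is smaller than the ratio of its TPM values.

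Named genes were chosen by a rule written before the data were examined. It takes 15 genes tied to the study's title, the 10 higher and the 10 lower genes with the largest log2 differences in each contrast, and up to 4 members of each gene list with the largest differences among those passing. The genes of the 10 highest and 10 lowest had an adjusted p below 0.05 and a mean of at least 5 TPM, and, except for the interaction, the libraries of both groups did not overlap; 3 libraries against 3 do so by chance in 10% of cases. When no member of a list passed, up to 2 were named. The 20 gene lists were also fixed before the data were examined: thermomorphogenesis and PIF targets, auxin, brassinosteroid and gibberellin, evening complex and clock, heat shock, abscisic acid and osmotic stress, proline metabolism, cold regulon, salicylic acid synthesis, salicylic acid response, jasmonate, ethylene and early osmotic ERF network, cell wall expansion, cell cycle, photosynthesis, carbon starvation, flavonoid and anthocyanin, root markers, seed storage and reference genes. All 394 members were in the table. Each list was compared with the other genes by camera, with a preset correlation between genes of 0.01 and again with the correlation estimated, adjusted over the 20 lists. Members passing are counted over all genes and again adjusted over the list alone.

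The share of the warm response kept with mannitol was measured on genes chosen without the libraries used to measure it. For each replicate number, warm genes (adjusted p below 0.05 and an absolute log2 difference of at least 1) were called without that replicate. Their mean signed difference with mannitol was then divided by that in the left-out libraries. Overlaps between contrasts are given beside the number for independent draws. For the contrasts that share the 27°C libraries, 20 simulations of unchanged groups gave the covariance that shared libraries alone bring.

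Replicate numbers were tested for pairing, and the residuals of libraries with the same number in different groups had correlations across genes between -0.076 and 0.13, with a median of -0.015. Libraries with different numbers had a median of 0.0079 and a highest value of 0.073. The highest pairs were replicates 1 (0.13) and replicates 2 (0.12) of 21°C and 27°C, so pairing of these groups is not excluded. Only 4 of 12 libraries matched best with their own number, and the samples were not treated as paired. The fit with the replicate number as a block is among the alternatives.

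On simulated data, with normal noise of each gene's measured spread around its mean, the warm contrast found 39 of 67 genes changed by 0.5 on the log2 scale and 65 of 67 changed by 1, with 7 calls among 19805 unchanged genes. The interaction found 9 of 67 genes at 0.5 and 55 of 66 at 1, with 4 calls among 19805. A simulated kept share of 0.5 was returned as 0.485. Only 200 of 20005 genes were changed in these simulated data, whereas 8958 passed for warmth and 1024 for the interaction in the real libraries. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so the counts found and falsely called do not carry over to the real contrasts.

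Alternatives were other pseudocounts, no filter and a stricter filter, median-of-ratios rescaling of the TPM values, quantile normalization, the replicate block, no mean-variance trend, array weights, fits of only the groups compared, an added minimum fold change and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.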

Results

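The data are expression values of 27655 genes in whole seedlings of Arabidopsis thaliana, the labels naming no separate tissue. The 12 libraries fall into 4 groups of 3: 21°C, 21°C with mannitol, 27°C, and 27°C with mannitol. The series asks how osmotic stress changes the growth response of seedlings to warmth, and its title names salicylic acid and the clock protein ELF3. All libraries were collected 12 h after the treatments began, which is 13 h after lights on. Reads recovered from the TPM values came to between 13471976 and 14565660 per library, and between 18762 and 19640 genes had at least 1 TPM. In what follows, ± is the SE of the fit for log2 differences and the SD of 3 libraries for TPM.

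The libraries separated by group along the leading principal components, which held 48.0% and 28.7% of the variance. The share of TPM held by the 50 most abundant genes differed between groups, from 19.5% in 21°C replicate 1 to 13.7% in 27°C with mannitol replicate 2. RBCS1A, a small subunit of the carbon-fixing enzyme Rubisco, was the top gene in these libraries and went from 32067 to 19210 TPM. Since TPM values share a fixed sum, a fall of such genes raises the values of the rest. Median-of-ratios rescaling lowered log2 differences by 0.089 for warmth, 0.10 for mannitol at 21°C, 0.19 for mannitol at 27°C, 0.17 for warmth with mannitol and 0.086 for the interaction. The split of all passing genes into higher and lower is given both ways for each contrast.

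Warmth alone, 27°C against 21°C, asks what the seedlings do without osmotic stress. Transcripts tied to warm growth rose together. PIF4 (AT2G43010), the transcription factor that drives elongation in warmth, rose from 2.2 ± 0.20 to 10.1 ± 0.94 TPM, a log2 difference of 1.79 ± 0.16 (adjusted p = 5.75e-07). Its targets YUC8 (AT4G28720), an auxin synthesis enzyme, and IAA29 (AT4G32280), an auxin response repressor, rose by 2.47 ± 0.18 (adjusted p = 1.14e-07) and 2.42 ± 0.12 (adjusted p = 3.31e-09). IAA19 (AT3G15540) rose by 1.60 ± 0.16 and the shade and growth marker ATHB2 (AT4G16780) by 1.05 ± 0.12. In the list of thermomorphogenesis and PIF targets, 15 of 17 tested members rose and 0 fell, with a median of 1.49 (adjusted p = 3.80e-08); adjusted over the list alone, 15 rose and 1 fell. The auxin list shares YUC8, YUC9, IAA19, IAA29 and SAUR22 with it, and 23 of its 33 members rose and 3 fell (median 0.76, adjusted p = 3.47e-05), against 24 and 3 adjusted over the list alone. Both calls held with an estimated correlation, at adjusted p = 0.00442 and adjusted p = 0.0167. Examples are the small auxin-induced transcripts SAUR22 (AT5G18050), at 2.13 ± 0.29, and SAUR24, at 1.94 ± 0.28. How reads shared between near-identical SAUR copies were assigned is not given in the sources used here.

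Clock and evening complex transcripts were higher at 27°C as well. All libraries were collected at 1 time, 13 h after lights on and in the dark. For these cycling genes, and for any gene of the other lists that cycles, no contrast here can tell a higher level from a shifted phase. LUX (AT3G46640), the DNA-binding member of the evening complex, rose from 5.96 ± 0.68 to 42.0 ± 1.3 TPM (2.63 ± 0.10, adjusted p = 1.29e-10), and its partner ELF4 (AT2G40080) rose by 0.78 ± 0.08 (adjusted p = 4.61e-06). ELF3 (AT2G25930) stood at 65.6 ± 3.91 TPM at 21°C and 73.8 ± 12 at 27°C, which did not pass (0.16 ± 0.10, adjusted p = 0.207). Of 26 tested list members, 22 rose and 0 fell, over all genes and adjusted over the list alone (median 0.88, adjusted p = 5.69e-09, and adjusted p = 0.00478 with an estimated correlation). The Myb-like clock factor RVE4 rose by 1.52 ± 0.10, and CDF2, a repressor of flowering, by 1.64 ± 0.18. Cell wall loosening genes showed 11 higher and 2 lower of 20, the same adjusted over the list alone, among them XTH24 at 2.33 ± 0.20 and EXPA8 at 1.49 ± 0.07 (median 0.46, adjusted p = 0.00533). That call was lost at adjusted p = 0.108 with an estimated correlation. In the brassinosteroid and gibberellin list 10 of 17 rose and 1 fell, and 12 and 1 adjusted over the list alone. The riser CPD, a brassinosteroid synthesis enzyme, stood at 0.85 ± 0.06, and GA3OX1, which makes active gibberellin, fell by 1.42 ± 0.11. The list's median was 0.36 (adjusted p = 0.0165, and adjusted p = 0.214 with an estimated correlation). Cell cycle genes went down, with 10 of 16 lower and 1 higher, the same adjusted over the list alone. The replication clamp PCNA1 fell by 0.99 ± 0.14 and the mitotic cyclin CYCB1;1 by 0.91 ± 0.10 (list median -0.45, adjusted p = 0.000134, and adjusted p = 0.0932 with an estimated correlation).

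**Figure D1:**
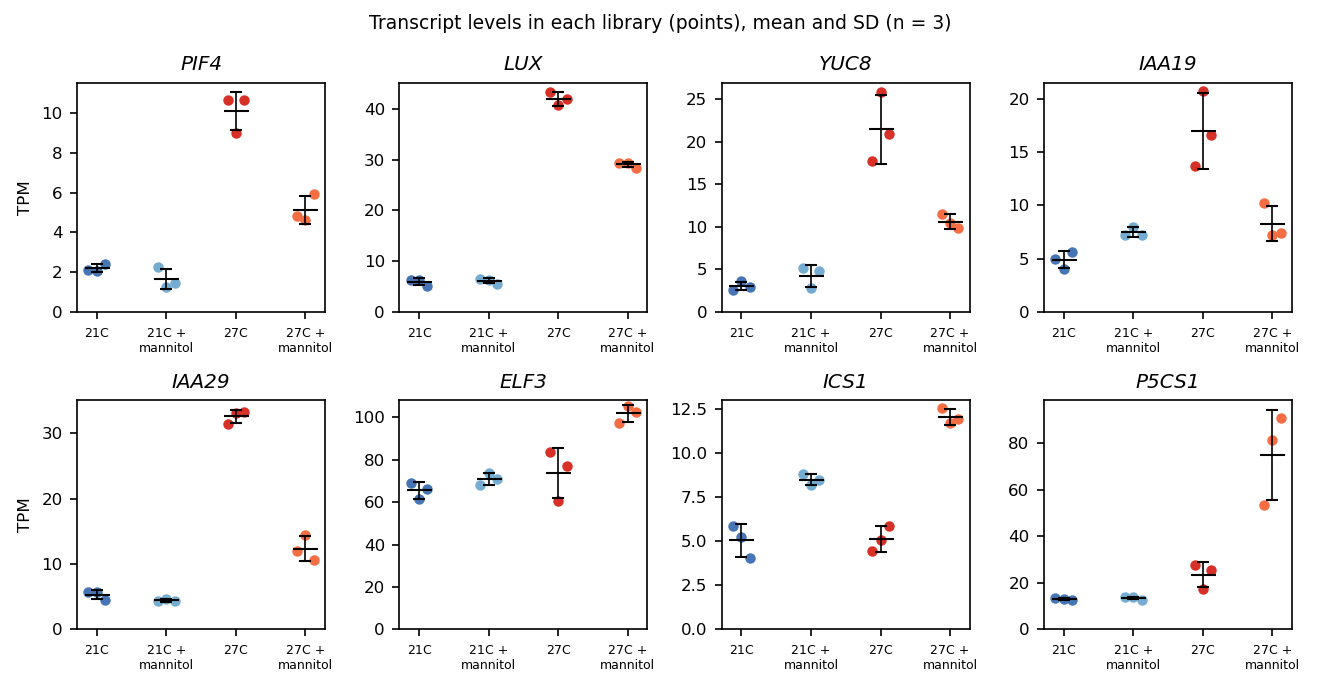
TPM in each library (points) with the mean and SD of 3 libraries for PIF4, LUX, YUC8, IAA19, IAA29, ELF3, ICS1 and P5CS1 in the 4 groups. IAA29 went from 5.32 to 32.6 TPM with warmth and stood at 12.4 TPM in warmth with mannitol.

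Stress transcripts changed at 27°C without mannitol too. The chaperone HSP70 (AT3G12580) rose from 7.77 ± 0.94 to 89.3 ± 5.54 TPM (3.37 ± 0.09, adjusted p = 4.83e-12), and 16 of 22 heat shock list members rose and 1 fell, over all genes and adjusted over the list alone. HSP90.1 was at 3.31 ± 0.11 and HSP17.4 at 2.99 ± 0.23 (list median 0.94, adjusted p = 3.47e-05, and adjusted p = 0.108 with an estimated correlation). Transcripts of late seed maturation were among the genes that rose most. The embryo protein M17 (AT2G41260) went from 0.761 ± 1.09 to 46 ± 9.05 TPM (4.89 ± 0.39, adjusted p = 2.19e-07). The tonoplast channel BETA-TIP rose by 3.97 ± 0.24, the dehydrin RAB18 (AT5G66400) by 3.53 ± 0.33 and the abscisic acid marker RD29B (AT5G52300) by 3.63 ± 0.40. The seed storage list, with 4 tested members, had 1 higher and 0 lower in both adjustments (median 1.42, adjusted p = 0.256), the oil body protein OLEO2 at 2.63 ± 0.37. In the abscisic acid and osmotic list 24 of 42 rose and 6 fell, and 26 and 6 adjusted over the list alone (median 0.36, adjusted p = 0.0461, and adjusted p = 0.417 with an estimated correlation). Leaving out 21°C replicate 3, 27°C replicate 2 or 27°C with mannitol replicate 3 ended that call, at adjusted p = 0.0505, 0.115 and 0.0529. NCED3 (AT3G14440), the rate-limiting enzyme of abscisic acid synthesis, was at 0.26 ± 0.21 (adjusted p = 0.317), while the proline synthesis enzyme P5CS1 (AT2G39800) rose by 0.77 ± 0.18 and RD29A (AT5G52310) fell by 0.92 ± 0.12. Among cold-regulated transcripts, which went both ways, COR15B (AT2G42530) fell from 35.8 ± 2.81 to 0.970 ± 0.151 TPM (-4.22 ± 0.18, adjusted p = 4.21e-10), COR15A (AT2G42540) by 3.3 ± 0.21 and KIN2 by 1.78 ± 0.22. The cold list had 3 higher and 5 lower of 10 in both adjustments, 1 and 5 with rescaling (median -0.47, adjusted p = 0.0165, and adjusted p = 0.174 with an estimated correlation).

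Among photosynthesis genes the light-harvesting copies moved apart. LHCB1.1 (AT1G29920) fell from 1106 ± 67.1 to 15.6 ± 2.77 TPM (-6.07 ± 0.13, adjusted p = 5.97e-13), whereas LHCB2.1 rose by 2.13 ± 0.11 and LHCB4.2 by 2.03 ± 0.05. Of 24 members 9 rose and 7 fell, and 10 and 8 adjusted over the list alone; with rescaling 7 rose and 9 fell. The list's median was 0.03 and its mean -0.10, and its test, which pointed down, did not pass (adjusted p = 0.649). The LHCB1 copies are nearly identical, and how reads shared between them were assigned is not given in the sources used here. Flavonoid genes went down, with 0 higher and 7 lower of 10, and 8 lower adjusted over the list alone (median -0.82, adjusted p = 6.20e-06, and adjusted p = 0.0156 with an estimated correlation). DFR and LDOX, which make anthocyanin precursors, fell by 1.83 ± 0.17 and 1.33 ± 0.16. Glucosinolate synthesis was represented by CYP79F1, which fell by 2.55 ± 0.26 (adjusted p = 2.38e-06). Carbon starvation markers had 11 higher and 1 lower of 15, and 12 and 1 adjusted over the list alone. The asparagine synthetase ASN1 rose by 1.36 ± 0.27 (list median 0.48, adjusted p = 0.00533, and adjusted p = 0.314 with an estimated correlation). The ethylene and ERF list had 14 of 23 higher and 1 lower in both adjustments, ACS8, an ethylene synthesis enzyme, at 2.73 ± 0.20 (list median 0.50, adjusted p = 0.00641, and adjusted p = 0.0961 with an estimated correlation).

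ICS1 (AT1G74710), the main salicylic acid synthesis enzyme, was at 5.05 ± 0.94 TPM at 21°C and 5.11 ± 0.73 at 27°C (0.02 ± 0.13, adjusted p = 0.915), a difference whose sign turned to -0.06 with rescaling. The salicylic acid synthesis list had 8 higher and 1 lower of 22 in both adjustments (median 0.29, adjusted p = 0.118), ICS2 at 1.19 ± 0.14. The response list had 3 higher and 3 lower of 16 in both adjustments (median -0.09, adjusted p = 0.175), the pathogenesis-related PR5 (AT1G75040) falling by 1.91 ± 0.16. PR1 (AT2G14610), the classic marker of the salicylic acid response, was listed at 0 TPM in every library of 3 groups and stayed below the filter. Jasmonate genes had 7 higher and 1 lower of 16, and 8 and 3 adjusted over the list alone, VSP1 at 1.34 ± 0.13 (median 0.15, adjusted p = 0.445). Proline genes had 4 higher and 2 lower of 6 in both adjustments (median 0.43, adjusted p = 0.612), with the breakdown enzyme PRODH1 falling by 0.71 ± 0.09. Root markers had 2 higher and 3 lower of 15 in both adjustments (median -0.17, adjusted p = 0.239), the nitrate transporter NRT2.1 falling by 1.06 ± 0.22. Of 12 reference genes, 3 were higher and 1 lower in both adjustments, but 1 higher and 3 lower with rescaling. UBQ10 stood at 0.54 ± 0.05 and EF1A at -0.55 ± 0.05; the median of the reference list was 0.01, and its test pointed down (adjusted p = 0.921). In all, 8958 of 20005 genes passed, 5636 higher and 3322 lower. With rescaling 8756 passed, 4405 higher and 4351 lower, and 7727 genes were called in the same direction both ways. A change of at least 2-fold was found for 773 higher and 255 lower genes. Each gene named here among the most changed had all 3 libraries of one group above all 3 of the other, which the naming rule required.

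Mannitol at 21°C asks what osmotic stress does in cool seedlings. Among the genes that rose most were a chitinase, glutathione transferases and an indole enzyme. The chitinase family gene AT2G43620 went from 1.47 ± 0.82 to 177 ± 12.8 TPM (6.22 ± 0.17, adjusted p = 6.07e-12). The glutathione transferases GSTF7 (AT1G02920) and GSTF6 (AT1G02930) rose by 5.07 ± 0.12 (adjusted p = 1.00e-12) and 4.86 ± 0.10 (adjusted p = 3.69e-13), and how reads shared between these similar copies were assigned is not stated. CYP71A12 (AT2G30750), an enzyme of indole defense compounds, rose by 5.05 ± 0.23. Among the genes that fell most, the lipase family gene AT5G33370 went from 19.2 ± 1.99 to 0.0974 TPM (-4.20 ± 0.15, adjusted p = 4.30e-11), and CER1 (AT1G02205), an enzyme of wax alkane synthesis, from 21.1 ± 2.07 to 1.66 ± 0.11 TPM (-3.05 ± 0.15, adjusted p = 1.16e-09). The myrosinase TGG2 (AT5G25980) fell by 2.18 ± 0.11.

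Salicylic acid transcripts were higher with mannitol at 21°C. ICS1 rose from 5.05 ± 0.94 to 8.48 ± 0.31 TPM (0.66 ± 0.13, adjusted p = 0.00238). In the synthesis list 14 of 22 rose and 1 fell, and 16 and 1 adjusted over the list alone (median 0.58, adjusted p = 2.16e-07, and adjusted p = 0.0790 with an estimated correlation). Examples are the regulator CBP60G, at 1.72 ± 0.19, and DLO1, which breaks salicylic acid down, at 2.77 ± 0.26. In the response list 15 of 16 rose and 0 fell in both adjustments, WRKY53 at 2.83 ± 0.21 and PR5 at 2.18 ± 0.16 (list median 1.57, adjusted p = 2.76e-11, and adjusted p = 0.00698 with an estimated correlation). In the ethylene and ERF list 17 of 23 rose and 0 fell, and 17 and 1 adjusted over the list alone, with ERF5 at 1.83 ± 0.16 and WRKY33 at 1.34 ± 0.11 (list median 0.70, adjusted p = 1.37e-07, and adjusted p = 0.00698 with an estimated correlation).

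Photosynthesis and flavonoid transcripts fell with mannitol at 21°C. Of 24 photosynthesis genes 19 fell and 1 rose, and 19 and 2 adjusted over the list alone, LHCB1.1 by 1.39 ± 0.13 and LHCB3 by 1.18 ± 0.10 (list median -0.30, adjusted p = 8.94e-15, and adjusted p = 0.00677 with an estimated correlation). Of 10 flavonoid genes 6 fell and 1 rose in both adjustments (median -0.45, adjusted p = 0.000646, and adjusted p = 0.0489 with an estimated correlation), DFR by 0.86 ± 0.17. Root markers had 5 higher and 0 lower in both adjustments, NRT2.1 at 2.52 ± 0.22 (list median 0.35, adjusted p = 0.0290, and adjusted p = 0.713 with an estimated correlation). That call ended without 21°C replicate 1, 21°C with mannitol replicate 3 or 27°C replicate 2, at adjusted p = 0.330, 0.0562 and 0.0510. The cell cycle list was lower with a median of -0.07 (adjusted p = 0.0156, and adjusted p = 0.301 with an estimated correlation). Its count was 0 higher and 2 lower over all genes and 0 adjusted over the list alone, and without 21°C with mannitol replicate 2 the list reached adjusted p = 0.117. The heat shock list had 7 higher and 0 lower in both adjustments (adjusted p = 0.0768, and adjusted p = 0.0158 with rescaling), HSP70 at 1.07 ± 0.09. With an estimated correlation and no rescaling that list reached adjusted p = 0.713. In the abscisic acid list 8 rose and 3 fell in both adjustments (median 0.06, adjusted p = 0.842), the dehydration marker RD22 at 1.78 ± 0.08; RD29B was at 0.53 ± 0.40 (adjusted p = 0.403) and P5CS1 at 0.04 ± 0.18 (adjusted p = 0.916, -0.06 with rescaling). PIF4, at -0.28 ± 0.16 (adjusted p = 0.238), and the thermomorphogenesis list, with 3 higher and 2 lower, and 5 and 3 adjusted over the list alone (median 0.34, adjusted p = 0.891), passed no test; with rescaling 2 were higher and 4 lower. In all 4011 genes passed, 3089 higher and 922 lower, against 2069 and 1907 with rescaling; 2991 were called in the same direction both ways.

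Mannitol at 27°C asks what osmotic stress does to warm seedlings. Several warm growth transcripts fell, while other members of that list rose. PIF4 went from 10.1 ± 0.94 to 5.13 ± 0.70 TPM (-0.86 ± 0.16, adjusted p = 0.000809) and IAA29 from 32.6 ± 1.01 to 12.4 ± 1.90 (-1.34 ± 0.12, adjusted p = 1.05e-06). YUC8 fell by 0.94 ± 0.18, IAA19 by 0.95 ± 0.16 and LUX by 0.51 ± 0.10 (adjusted p = 0.000926), while ELF3 rose from 73.8 ± 12 to 102 ± 4.08 TPM (0.47 ± 0.10, adjusted p = 0.00178). The wall enzyme XTH15 (AT4G14130) fell by 1.81 ± 0.13, from 84.2 ± 4.0 to 23.4 ± 0.65 TPM, and the growth regulator PRE1 (AT5G39860) by 1.59 ± 0.22. Of 17 thermomorphogenesis genes 8 fell and 4 rose, 10 and 2 with rescaling, and 8 and 5 adjusted over the list alone (median -0.25, adjusted p = 6.40e-05, and adjusted p = 0.0103 with an estimated correlation). Of 33 auxin genes 15 fell and 4 rose, and 16 and 4 adjusted over the list alone (median -0.32, adjusted p = 1.39e-08, and adjusted p = 0.00522 with an estimated correlation). Among the risers CYP79B2, which feeds both auxin and indole defense compounds, stood at 1.18 ± 0.06. The cell wall list had 4 higher and 8 lower of 20, and 6 and 8 adjusted over the list alone, XTH8 falling by 1.24 ± 0.08 and EXPA15 rising by 1.12 ± 0.10. Its median was 0.08, its mean -0.13, and its test pointed down (adjusted p = 0.00734). The call was lost at adjusted p = 0.168 with an estimated correlation and at adjusted p = 0.143 with quantile normalization.

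Genes that rose with mannitol at 27°C include AT2G43620, ICS1 and PR5. AT2G43620 went from 2.55 to 163 ± 8.84 TPM (5.54 ± 0.17, adjusted p = 3.13e-11), the copper protein BCB rose by 3.86 ± 0.33 and the lipid transfer protein LTP3 by 3.76 ± 0.16. ICS1 rose from 5.11 ± 0.73 to 12 ± 0.45 TPM (1.1 ± 0.13, adjusted p = 1.99e-05). In the synthesis list 16 rose and 0 fell, and 17 and 0 adjusted over the list alone, CBP60G at 2.16 ± 0.19 (list median 0.54, adjusted p = 0.000133, and adjusted p = 0.168 with an estimated correlation). In the response list 15 rose and 0 fell in both adjustments, PR5 at 2.53 ± 0.16 and WRKY53 at 2.83 ± 0.21 (list median 1.19, adjusted p = 2.81e-06, and adjusted p = 0.0269 with an estimated correlation). The glucanase PR2 was listed at 0 in all 27°C libraries and at 4.19 ± 0.60 TPM with mannitol. The ERF list had 12 higher and 2 lower, and 14 and 2 adjusted over the list alone, ERF5 at 1.54 ± 0.16 and ACS8 at -1.97 ± 0.20 (list median 0.56, adjusted p = 0.0465, and adjusted p = 0.168 with an estimated correlation). That call ended without 27°C replicate 1, 27°C replicate 3 or 27°C with mannitol replicate 2, at adjusted p = 0.117, 0.0537 and 0.0512.

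Small heat shock transcripts and P5CS1 rose with mannitol at 27°C. HSP17.6C (AT1G53540) went from 2.3 ± 0.077 to 19.0 ± 5.29 TPM (2.57 ± 0.19, adjusted p = 1.25e-07), and HSP17.4 rose by 2.2 ± 0.23. The heat shock list had 15 of 22 higher and 0 lower, 10 and 0 with rescaling, and 16 and 0 adjusted over the list alone (median 0.62, adjusted p = 0.000420, and adjusted p = 0.168 with an estimated correlation). P5CS1 rose from 24 ± 5.55 to 75.0 ± 19.3 TPM (1.62 ± 0.18, adjusted p = 6.80e-06). The proline list had 4 of 6 higher and 0 lower in both adjustments, 2 and 0 with rescaling, and did not pass its test (median 0.29, adjusted p = 0.0643). RD22 rose by 2.29 ± 0.08. The abscisic acid list, with 19 higher and 5 lower, and 22 and 6 adjusted over the list alone (median 0.34), did not pass its test (adjusted p = 0.277). Photosynthesis transcripts fell, 21 of 24 with 0 higher, against 22 lower and 1 higher adjusted over the list alone. LHCB1.2 (AT1G29910) went from 2091 ± 258 to 367 ± 22.0 TPM (-2.50 ± 0.08, adjusted p = 3.45e-11) and LHCA3 fell by 1.15 ± 0.05 (list median -0.58, adjusted p = 3.80e-27, and adjusted p = 0.000785 with an estimated correlation). The ferric reductase FRO2 (AT1G01580) fell from 95.7 ± 15.4 to 16.0 ± 5.55 TPM (-2.54 ± 0.38, adjusted p = 0.000162) and the iron transporter IRT1 (AT4G19690) by 1.92 ± 0.31. IRT1 is also a root marker; in that list 7 rose and 2 fell, and 8 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.416). The cell cycle list had 5 higher and 0 lower in both adjustments, but 0 of either with rescaling, and did not pass its test (adjusted p = 0.559). In all 6905 genes passed, 5544 higher and 1361 lower. With rescaling 5329 passed, 2346 higher and 2983 lower, so the excess of higher genes turned, and 3707 were called in the same direction both ways.

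The mannitol responses at both temperatures overlapped. Among the shared genes were AT2G43620, GSTF7, PR5 and WRKY53, which rose, and CER1, AT5G33370 and the beta-glucosidase BGLU18, which fell. In all, 2138 genes were higher in both (856 for independent draws) and 452 lower in both (62.7), 2590 together, while 108 changed in opposite directions. Across genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.646 and a Spearman correlation of 0.495.

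Warmth with mannitol, 27°C against 21°C in stressed seedlings, asks how much of the warm response remains under stress. PIF4 rose by 1.22 ± 0.16 (adjusted p = 1.72e-05), LUX by 2.07 ± 0.10 (adjusted p = 1.10e-09), YUC8 by 1.17 ± 0.18 (adjusted p = 9.06e-05) and IAA29 by 1.28 ± 0.12 (adjusted p = 9.47e-07). IAA19 was at 0.12 ± 0.16 (adjusted p = 0.549), a sign that turned to -0.04 with rescaling and -0.02 without 27°C with mannitol replicate 1. ELF3 rose by 0.52 ± 0.10, P5CS1 by 2.36 ± 0.18 and HSP17.4 by 4.84 ± 0.23 (adjusted p = 1.60e-09). LHCB1.1 fell by 6.20 ± 0.13 and COR15A by 4.08 ± 0.21. ICS1, at 0.46 ± 0.13 (adjusted p = 0.00876), lost its call with rescaling (adjusted p = 0.0882). The thermomorphogenesis list had 11 higher and 0 lower in both adjustments (median 0.66, adjusted p = 0.00142, and adjusted p = 0.0448 with an estimated correlation). The clock list had 22 higher and 0 lower, and 23 and 0 adjusted over the list alone (median 0.93, adjusted p = 2.76e-06, and adjusted p = 0.0299 with an estimated correlation). The auxin list, with 17 higher and 3 lower in both adjustments (median 0.36), did not pass its test (adjusted p = 0.108) but did so with rescaling (adjusted p = 0.0386). With an estimated correlation and no rescaling it reached adjusted p = 0.313.

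Calls that were lost with an estimated correlation came from 8 further lists, whose counts were the same adjusted over the list alone except where given. The heat shock list had 18 higher and 1 lower, and 19 and 1 adjusted over the list alone (median 0.93, adjusted p = 7.42e-06, then adjusted p = 0.137 with an estimated correlation). Flavonoid genes had 0 higher and 6 lower, DFR falling by 1.38 ± 0.17 (list median -0.49, adjusted p = 0.00142, then adjusted p = 0.0759 with an estimated correlation). Photosynthesis genes had 6 higher and 11 lower, LHCB2.1 at 1.77 ± 0.11 and LHCB3 at -2.05 ± 0.10 (list median -0.08, adjusted p = 0.00297, then adjusted p = 0.154 with an estimated correlation and adjusted p = 0.514 with quantile normalization). Cold genes had 3 higher and 6 lower, KIN1 falling by 2.69 ± 0.17 (list median -0.47, adjusted p = 0.0107, then adjusted p = 0.177 with an estimated correlation and adjusted p = 0.0517 with quantile normalization). Carbon starvation genes had 10 higher and 1 lower, ASN1 at 1.78 ± 0.27 (list median 0.74, adjusted p = 0.0314, then adjusted p = 0.465 with an estimated correlation). The abscisic acid list, with 27 higher and 8 lower, and 29 and 8 adjusted over the list alone (median 0.58, adjusted p = 0.0441), reached adjusted p = 0.437 with an estimated correlation. It lost its call without 21°C with mannitol replicate 2 (adjusted p = 0.0575), 27°C replicate 2 (adjusted p = 0.0629) or 27°C with mannitol replicate 3 (adjusted p = 0.0690). The salicylic acid response list, with 2 higher and 5 lower, and WRKY18 falling by 1.55 ± 0.11, had a median of -0.10 (adjusted p = 0.0482). Its call was lost with rescaling (adjusted p = 0.143), with an estimated correlation (adjusted p = 0.313), and without 21°C replicate 1 (adjusted p = 0.0592), 21°C replicate 3 (adjusted p = 0.0506), 21°C with mannitol replicate 1 (adjusted p = 0.0531) or 21°C with mannitol replicate 3 (adjusted p = 0.141). The cell cycle list, with 2 higher and 7 lower, and 2 and 8 adjusted over the list alone (median -0.15, adjusted p = 0.0482), reached adjusted p = 0.362 with an estimated correlation. It also lost its call without replicates 1 or 3 of 21°C (adjusted p = 0.0592 and 0.0506), 1 or 3 of 21°C with mannitol (adjusted p = 0.0831 and 0.0736), or 2 or 3 of 27°C with mannitol (adjusted p = 0.0718 and 0.0838). In all 10802 genes passed, 7496 higher and 3306 lower, against 4606 and 5075 with rescaling; 7912 were called in the same direction both ways.

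The interaction asks whether the warm response differed with mannitol, the question nearest to the title. For IAA19, YUC8 and IAA29, which rose with warmth, that rise was smaller with mannitol. IAA19 also rose with mannitol at 21°C, which is part of its interaction, but 9 alternatives ended that call. The interaction was -1.48 ± 0.23 for IAA19 (adjusted p = 0.00127), -1.29 ± 0.26 for YUC8 (adjusted p = 0.00862) and -1.14 ± 0.17 for IAA29 (adjusted p = 0.00111). XTH15 stood at -1.48 ± 0.18, and GH3.3, which conjugates auxin, at -1.38 ± 0.14 (adjusted p = 5.77e-05). PIF4 itself, at -0.57 ± 0.22, did not pass (adjusted p = 0.170), nor did ELF3, at 0.36 ± 0.14 (adjusted p = 0.158), ELF4, at -0.24 ± 0.12 (adjusted p = 0.287), or ICS1, at 0.44 ± 0.19 (adjusted p = 0.209). LUX passed at -0.56 ± 0.14 (adjusted p = 0.0273), a call lost in 7 of 12 fits that leave out a library each, those without replicate 3 of 21°C (adjusted p = 0.0563), replicates 1 and 2 of 21°C with mannitol (adjusted p = 0.0718 and 0.0609), replicate 3 of 27°C (adjusted p = 0.0618) and replicates 1, 2 and 3 of 27°C with mannitol (adjusted p = 0.0573, 0.0628 and 0.0727). The thermomorphogenesis list had 0 above and 7 below 0, and 1 and 9 adjusted over the list alone (median -0.57, adjusted p = 1.15e-05, and adjusted p = 0.00943 with an estimated correlation). The auxin list had 2 above and 9 below, and 3 and 15 adjusted over the list alone (median -0.41, adjusted p = 2.87e-06, and adjusted p = 0.00992 with an estimated correlation). Photosynthesis genes had 0 above and 8 below, and 0 and 13 adjusted over the list alone, LHCB1.2 at -1.83 ± 0.11 (list median -0.23, adjusted p = 7.90e-11, and adjusted p = 0.00943 with an estimated correlation).

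Genes with an interaction above 0 include P5CS1 at 1.59 ± 0.25 (adjusted p = 0.00149), TGG2 at 1.77 ± 0.16 (adjusted p = 3.35e-05) and HSP17.6C at 2.49 ± 0.26 (adjusted p = 7.07e-05). The HSP17.6C call was lost with a pseudocount of 0.1 and with voom, at adjusted p up to 0.271. Among the most negative were the indole enzyme CYP71A12 at -3.54 ± 0.33 (adjusted p = 3.47e-05) and NAS2 (AT5G56080) at -3.07 ± 0.46, FRO2 at -2.76 ± 0.54 and IRT1 at -2.49 ± 0.43 (adjusted p = 0.00338). IRT1 spread widely at 21°C, at 159 ± 89.1 TPM. The root marker list holding IRT1 had 2 above and 2 below, and 3 and 2 adjusted over the list alone (adjusted p = 0.369). The ERF list had 0 above and 2 below, and 1 and 4 adjusted over the list alone, ACS8 at -2.10 ± 0.28 (list median -0.19, adjusted p = 0.00639, and adjusted p = 0.113 with an estimated correlation). The cell cycle list had 2 above and 0 below, 0 of either with rescaling, and 4 and 0 adjusted over the list alone (median 0.23, adjusted p = 0.00639, and adjusted p = 0.197 with an estimated correlation). The flavonoid list had 1 above and 0 below in both adjustments, FLS1 at 0.76 ± 0.14 (list median 0.31, adjusted p = 0.0126, and adjusted p = 0.129 with an estimated correlation), and lost its call without 27°C replicate 1 (adjusted p = 0.0904). Both salicylic acid lists were uncalled, at adjusted p = 0.204 for synthesis and adjusted p = 0.0620 for response.

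**Figure D2:**
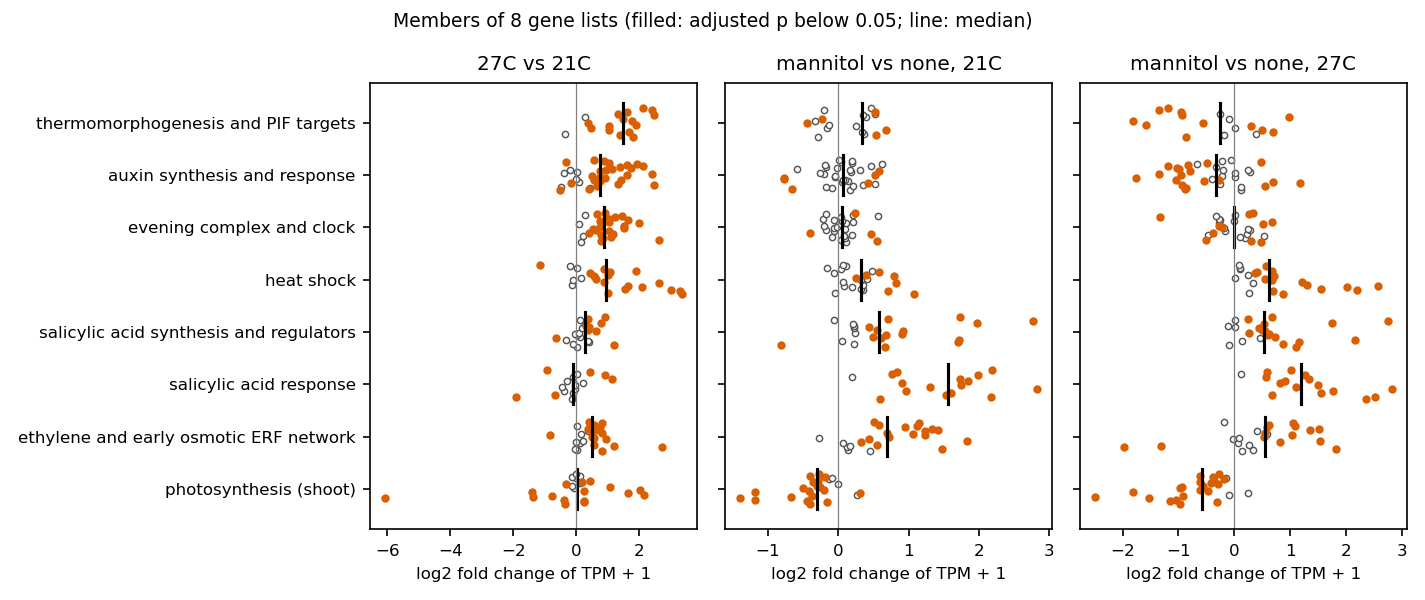
Log2 difference of each tested member of 8 gene lists for warmth, mannitol at 21°C and mannitol at 27°C, with filled points for an adjusted p below 0.05 and a line at the median. The thermomorphogenesis list has medians of 1.49, 0.34 and -0.25.

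In all 1024 genes passed the interaction, 486 above and 538 below 0, and rescaling gave 313 and 740. Of the 538 below 0, 277 were higher with mannitol at 21°C, while 322 were lower and 88 higher with mannitol at 27°C. A value below 0 can thus come from a rise with mannitol at 21°C as well as from a fall at 27°C. The count moved with single libraries, to 655 without 21°C with mannitol replicate 3, 667 and 666 without replicates 2 and 3 of 27°C with mannitol, and 1765 without 27°C replicate 1. Of the 773 genes at least 2-fold higher with warmth, IAA29, YUC8 and LUX among them, 671 were also higher with warmth under mannitol, and 138 had an interaction against the warm response and 19 one along it. Of the 255 at least 2-fold lower, LHCB1.1 and COR15A among them, 213 were also lower, 30 had an interaction against the warm response and 17 one along it. These genes were chosen by the warm contrast, which is part of the interaction, and that favors interactions against it. The share of the warm response kept with mannitol was 0.877 ± 0.017 (SD over 3 left-out replicates), at 0.847 ± 0.017 for the higher and 0.983 ± 0.013 for the lower genes. With genes chosen by adjusted p alone that order turned, at 1.02 for the higher and 0.903 for the lower genes. All 3 left-out values of the kept share use the same mannitol libraries. Its SD therefore leaves out the spread between those libraries and is not the uncertainty of the share.

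Genes that rose with warmth and fell when mannitol was added at 27°C include PIF4, LUX, YUC8, IAA19 and IAA29. There were 543 of them (383 for independent draws), and 779 fell with warmth and rose with mannitol (921 for independent draws). With rescaling these counts were 880 and 451, so their order turned. Both contrasts share the 27°C libraries, which pulls them apart, and how many opposite calls that adds was not tested. The covariance of their log2 differences across genes was -0.0058, against -0.0129 in simulations of unchanged groups.

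**Figure D3:**
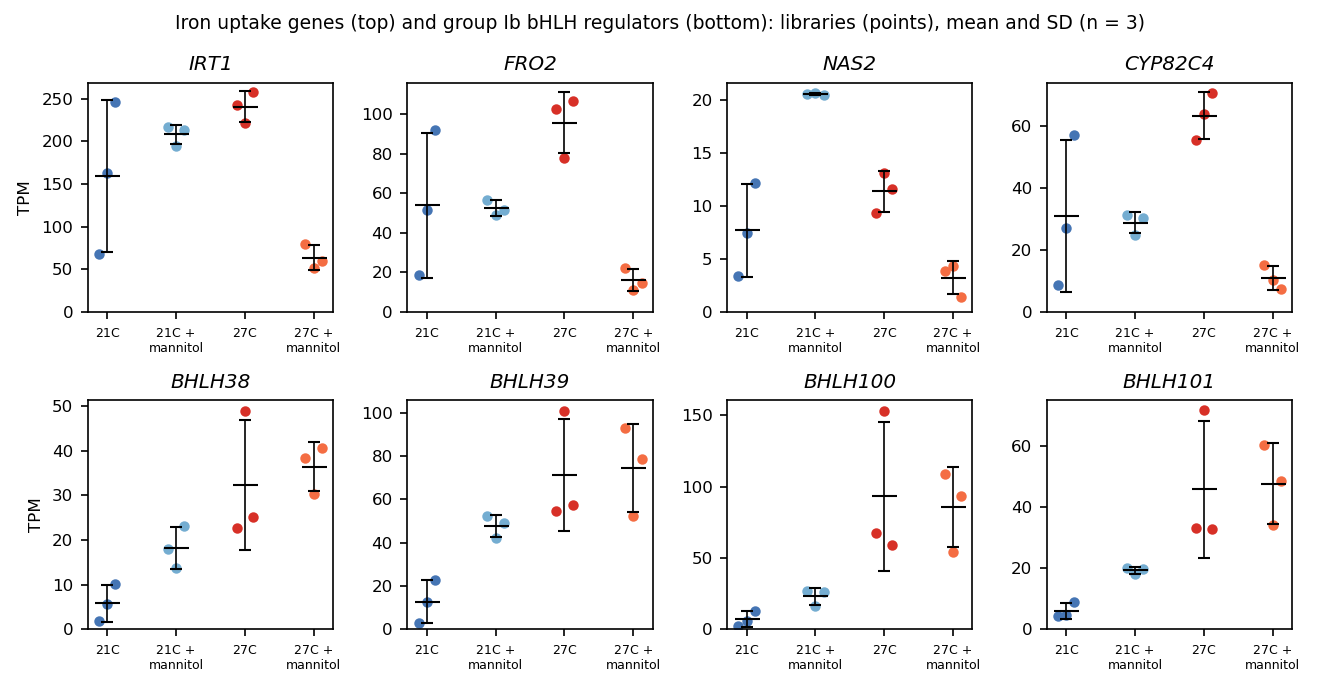
TPM in each library (points) with the mean and SD of 3 libraries in the 4 groups, for IRT1, FRO2, NAS2 and CYP82C4 above and the regulators BHLH38, BHLH39, BHLH100 and BHLH101 below. FRO2 stood at 95.7 TPM at 27°C and 16.0 TPM with mannitol.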

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

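The tests of the seed, iron and light-harvesting patterns, except the one that leaves out single libraries, and the regroupings with additive effects taken out were chosen only after the result was seen.

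The warm response differed with mannitol, by the interaction test, for 1024 genes. Below 0 were LUX at -0.56, YUC8 at -1.29, IAA19 at -1.48, IAA29 at -1.14, SAUR22 at -1.66, XTH15 at -1.48, PRE1 at -1.45 and GH3.3 at -1.38 on the log2 scale. Ethylene synthesis genes ACS8 and ACS11 stood at -2.10 and -1.48. LHCB1.2 was at -1.83, LHCA3 at -0.71, LHCB6 at -0.67 and LHCB3 at -0.64. The most negative were AT1G52120, a lectin family gene, at -4.27, CYP71A12 at -3.54, NAS2 at -3.07, FRO2 at -2.76, CYP82C4 at -2.71, AT1G13609 at -2.57, AT2G37030 at -2.56, IRT1 at -2.49, PP2-A8 at -2.48 and AT1G26380 at -2.24. Above 0 were P5CS1 at 1.59, HSP17.6C at 2.49, HSP17.4 at 1.85, TGG2 at 1.77, COR413IM1 at 1.63, AT5G38020 at 1.5, AT5G10210 at 1.47, AT3G59340 at 1.44 and Hsp70b at 1.43. FLS1 was at 0.76, and the cell cycle genes MCM2 and CYCD3;1 at 0.58 and 0.39. AT5G23115 had a fitted value of 5.18 but was listed at 0 in every library of 21°C with mannitol, so that value is no measure of size. Gene lists differed with medians of -0.57 for thermomorphogenesis, -0.41 for auxin, -0.19 for the ERF network, 0.23 for cell cycle, -0.23 for photosynthesis and 0.31 for flavonoids. With an estimated correlation the calls of the ERF, cell cycle and flavonoid lists were lost (adjusted p = 0.113, 0.197 and 0.129), and with rescaling 0 cell cycle members passed.

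Several of these calls ended when 1 library at a time was left out, each replicate below standing for a separate fit. The count itself was 655 without replicate 3 of 21°C with mannitol, 667 and 666 without replicates 2 and 3 of 27°C with mannitol, and 1765 without replicate 1 of 27°C. The call was lost for LUX without replicate 3 of 21°C (adjusted p = 0.0563), replicates 1 and 2 of 21°C with mannitol (adjusted p = 0.0718 and 0.0609), replicate 3 of 27°C (adjusted p = 0.0618) and replicates 1, 2 and 3 of 27°C with mannitol (adjusted p = 0.0573, 0.0628 and 0.0727). For AT5G23115 it was lost without replicate 1 of 21°C (adjusted p = 0.0592), replicates 1, 2 and 3 of 21°C with mannitol (adjusted p = 0.0574, 0.0561 and 0.0597), replicate 3 of 27°C (adjusted p = 0.0702) and replicates 1 and 3 of 27°C with mannitol (adjusted p = 0.0664 and 0.0635). For SAUR22 it ended without replicate 1 of 21°C (adjusted p = 0.0554), replicate 2 of 21°C with mannitol (adjusted p = 0.0637), replicates 2 and 3 of 27°C (adjusted p = 0.0627 and 0.0721) and replicates 1 and 2 of 27°C with mannitol (adjusted p = 0.0728 and 0.0630). AT5G10210 lost its call without replicates 2 and 3 of 21°C (adjusted p = 0.0598 and 0.0582), replicates 2 and 3 of 21°C with mannitol (adjusted p = 0.0643 and 0.0519) and replicates 2 and 3 of 27°C with mannitol (adjusted p = 0.0712 and 0.0747). AT5G38020 lost it without replicates 2 and 3 of 21°C (adjusted p = 0.0797 and 0.0909), replicate 2 of 21°C with mannitol (adjusted p = 0.0577), replicates 1 and 3 of 27°C (adjusted p = 0.0555 and 0.0704) and replicates 1, 2 and 3 of 27°C with mannitol (adjusted p = 0.0997, 0.101 and 0.0572). AT1G13609 lost it without replicate 2 of 21°C (adjusted p = 0.0820), replicates 1, 2 and 3 of 21°C with mannitol (adjusted p = 0.0988, 0.0677 and 0.102), replicates 2 and 3 of 27°C (adjusted p = 0.0934 and 0.0517) and replicates 1, 2 and 3 of 27°C with mannitol (adjusted p = 0.0620, 0.116 and 0.0893). CYP82C4 lost it without replicate 3 of 27°C with mannitol (adjusted p = 0.0546) and LHCB3 without replicate 3 of 21°C with mannitol (adjusted p = 0.0613) and replicates 2 and 3 of 27°C with mannitol (adjusted p = 0.0532 and 0.0510). MCM2 lost it without replicates 2 and 3 of 21°C (adjusted p = 0.0918 and 0.0796), replicates 1, 2 and 3 of 21°C with mannitol (adjusted p = 0.0823, 0.0714 and 0.0867) and replicates 1, 2 and 3 of 27°C with mannitol (adjusted p = 0.0856, 0.0798 and 0.0734). CYCD3;1 lost it without replicates 1 and 2 of 21°C (adjusted p = 0.0740 and 0.0678), replicates 1, 2 and 3 of 21°C with mannitol (adjusted p = 0.0549, 0.0793 and 0.0678), replicate 3 of 27°C (adjusted p = 0.0814) and replicates 1 and 3 of 27°C with mannitol (adjusted p = 0.0850 and 0.0746). With the replicate number as a block, AT5G38020, AT1G13609 and MCM2 lost their calls too (adjusted p = 0.0533, 0.0524 and 0.0535). The flavonoid list lost its call without replicate 1 of 27°C (adjusted p = 0.0904), with a pseudocount of 0.1 (adjusted p = 0.0543), with array weights (adjusted p = 0.0953) and with voom (adjusted p = 0.0529), and the ERF list with array weights (adjusted p = 0.0760). Rescaling ended the calls of AT5G38020, MCM2 and CYCD3;1 (adjusted p = 0.0575, 0.0557 and 0.113), and quantile normalization those of AT1G13609 and MCM2 (adjusted p = 0.0571 and 0.0573). A pseudocount of 0.1 ended those of HSP17.6C, HSP17.4, PRE1, AT5G38020, AT1G13609 and SAUR22 (adjusted p = 0.0664, 0.633, 0.0585, 0.0593, 0.0559 and 0.0805). Voom ended those of HSP17.6C, HSP17.4, PRE1, AT5G23115, AT5G10210, SAUR22 and CYCD3;1 (adjusted p = 0.271, 0.799, 0.107, 0.0796, 0.0604, 0.0889 and 0.0751). Without a filter AT5G23115, AT5G38020, AT5G10210, AT1G13609, SAUR22 and MCM2 lost theirs (adjusted p = 0.0589, 0.0824, 0.0533, 0.0902, 0.0502 and 0.0540). Without a mean-variance trend these 6 lost theirs too (adjusted p = 0.0674, 0.0890, 0.0525, 0.0993, 0.0513 and 0.0589), as did CYP82C4, CYCD3;1 and LHCB3 (adjusted p = 0.0531, 0.0629 and 0.0635).

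The samples were also regrouped to ask how often other groupings gave as many genes. For warmth, mannitol at 21°C, mannitol at 27°C and warmth with mannitol, 1 of 10 splits, the real one, gave as many genes, 8958, 4011, 6905 and 10802, against at most 0, 1, 0 and 0 in other splits. With 10 splits the share cannot fall under 0.05. For the interaction, 8 of 100 regroupings, the real one included, gave at least 1024 genes, the highest other 12484, so this test does not exclude chance. The 7 others each left 1 mannitol level as labelled or exchanged it whole, called between 1900 and 12484 genes, and so point to the temperature structure of the samples. The 75 drawn with both levels mixed gave at most 0. In a test added after that outcome, the additive effects of warmth and mannitol were taken out first. Then 1 of 100 regroupings, the real one, gave as many, the highest other 0. The real grouping keeps its 1024 genes in that step. Regroupings that left 1 mannitol level as labelled or exchanged it whole lost the effect they exchanged, that with 12484 genes among them. Their 0 was therefore set by the step itself. The test was also chosen after the planned one did not exclude chance, so it does not exclude chance either.

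Late seed maturation transcripts, a group put together after the values were seen, were higher at 27°C. M17, RAB18, RD29B, PER1, BETA-TIP and EM1 had a median log2 difference of 3.58, and of 3.46 with mannitol. Because of that choice these medians are descriptions only. The seed storage list fixed before the data were examined did not pass its camera test for warmth (adjusted p = 0.256). Seeds that still hold storage transcripts cannot be told apart as a source: the 11 storage transcripts had a median of -0.063, but 8 of them lay below 1 TPM at 27°C, too near 0 to decide. Their summed level was 21.6 TPM at 27°C against 8.98 at 21°C, while the 6 transcripts summed to 302 against 21.8. An abscisic acid response at 27°C cannot be told apart from other causes here: the 40 list members outside the pattern had a median of 0.32 with quartiles of -0.02 and 0.80, and the members went both ways. RAB18 and RD29B belong to that list too but were counted in the pattern, so this test left them out. They held 137 and 69.6 of the 302 TPM at 27°C. A biological effect of warmth stays open as well.

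Iron uptake transcripts, a group put together after the values were seen, were lower in 27°C with mannitol than in 27°C: IRT1, FRO2, NAS2, CYP82C4, COPT2 and the regulators FRU, MYB10 and MYB72 lay between -2.54 and -0.92, with a median of -1.58 (log2). A smaller share of root tissue would lower other root markers, but the 14 markers other than IRT1 had a median of 0.34 and a lower quartile of 0.05, which argues against it. Lower transcripts of the group Ib bHLH regulators are argued against by their median of 0.10, between -0.05 and 0.24, but their partner FRU fell by 1.16 and MYB10 and MYB72 by 0.92 and 1.15, so lower regulators of other kinds stay open. A single deviating library is argued against as well, since at least 7 of the 8 passed in each of 12 fits that left out 1 library. For the interaction all 8 passed, and at least 6 did with 1 left out (6 without replicate 3 of 27°C with mannitol). NAS2, FRO2, CYP82C4 and IRT1 were among the interaction's most negative genes, so these counts are no separate support. All 8 also climbed from replicate 1 to replicate 3 of 21°C, a group within the interaction, IRT1 at 68.4, 163 and 247 TPM. An effect of mannitol on iron uptake at 27°C may remain, as a hypothesis.

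LHCB1.1 was lower at 27°C, from 3.05% to 0.079% of the summed LHCB1 TPM, and from 1.57% to 0.049% with mannitol. Shared reads reassigned between the LHCB1 copies would leave their sum as it was, but the sum fell from 36313 ± 433 to 19648 ± 997 TPM, a log2 difference of -0.89. LHCB1.1 held only 3.05% of that sum at 21°C, so the other copies set its fall. Reassigned reads do not account for the fall of the sum. Whether LHCB1.1 lost reads to the other copies cannot be decided from it, since so small a share would hardly move the sum. If shared reads were dropped in counting, the sum need not hold, so the test cannot decide that case either. With mannitol the sum went from 26880 ± 1769 to 9603 ± 154 TPM, a difference of -1.48. A general fall of photosynthesis transcripts at 27°C is argued against by the 21 list members outside LHCB1, with a median of 0.13 and quartiles of -0.13 and 0.25. How reads were divided between the copies, which could set the size of the LHCB1.1 change, and a biological effect of warmth on this copy both stay open.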

How the results depend on the processing

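Of the alternatives, voom on recovered reads was chosen after seeing the data. The edgeR and DESeq2 alternative was not run because the table holds no counts, and no fit of only the groups compared exists for the interaction. Of 465 results for named genes 436 passed as reported, and 356 of these kept direction and call in each of the alternatives run; of 43 list calls 31 did so apart from the estimated correlation, which ended 26. Named genes lost 35 calls with rescaling, 33 with quantile normalization, 26 with voom and 25 with no mean-variance trend, and between 6 and 28 when 1 library was left out. Array weights, whose estimation stopped before full convergence, moved the genes passing to 12377 for mannitol at 27°C and 4125 for the interaction, the shared mannitol response to 4080 and the warm-induced genes lowered by mannitol to 1366. With an absolute log2 difference of at least 1 required, 1028, 747, 834, 1304 and 306 genes passed for warmth, mannitol at 21°C, mannitol at 27°C, warmth with mannitol and the interaction, since that removes small changes. Rescaling took the warm-induced genes lowered by mannitol to 880. The kept share was 0.850 with rescaling, 0.851 with a pseudocount of 5, 0.804 with genes chosen and measured on all libraries and 0.982 with adjusted p alone for choosing genes, where the share of the higher genes (1.02) lay above that of the lower genes (0.903), the reverse of the order reported. With the replicate block the counts were 8811, 3816, 6695, 10691 and 959, with 2456 shared genes, 530 lowered genes and a kept share of 0.878. The cause was not tested except where said. Depth stood at 13471976 recovered reads or more per library, and how it limits the calls was not tested. Simulated interactions of 0.25 on the log2 scale were found in 1.49% of cases, in data with only 200 changed genes.

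The values below belong to genes whose sign turned and to lists whose test turned direction. For a list the value is the mean of the members minus that of other genes, which need not change sign when the test does. All were uncalled both ways, except ACT7, which passed as reported. With a pseudocount of 5, HSP70 in the interaction was at 0.031 and the thermomorphogenesis list in mannitol at 21°C at -0.014. Without a filter, seed storage in warmth was at 0.219 and reference genes in mannitol at 27°C at -0.068. With a minimum of 5 TPM, thermomorphogenesis and auxin in mannitol at 21°C were at -0.018 and -0.019, and seed storage in the interaction at 0.503. Rescaling gave -0.059 for ICS1 in warmth, -0.047 and -0.062 for LUX and P5CS1 in mannitol at 21°C, -0.0056 and -0.048 for RD29A and ACT7 in mannitol at 27°C and -0.043 for IAA19 in warmth with mannitol. For lists it gave 0.168, -0.024 and -0.013 for cold, jasmonate and reference genes in mannitol at 21°C, 0.057 for seed storage in mannitol at 27°C and 0.036 for jasmonate in warmth with mannitol. Quantile normalization gave -0.107 for ICS1 in warmth, -0.141 and -0.103 for LUX and P5CS1 in mannitol at 21°C, -0.091 for RD29A in mannitol at 27°C and -0.076 for IAA19 in warmth with mannitol. For lists it gave -0.085 and 0.0042 for photosynthesis and reference genes in warmth, 0.195 and -0.035 for cold and carbon starvation in mannitol at 21°C, and -0.042, -0.033 and 0.092 for cell cycle, seed storage and reference genes in mannitol at 27°C. Jasmonate in warmth with mannitol was at 0.018 with quantile normalization and 0.033 with only the groups compared. Array weights gave 0.020 for NCED3 in mannitol at 21°C and -0.069 for reference genes in warmth, and voom -0.013 for ICS1 in warmth.

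Leaving out 1 library at a time gave these ranges over 12 fits. Genes passing ran from 7684 to 9670 for warmth, 2749 to 4833 for mannitol at 21°C, 4975 to 7495 for mannitol at 27°C, 9338 to 11607 for warmth with mannitol and 655 to 1765 for the interaction. For that last count, the lowest value came without replicate 3 of 21°C with mannitol (655), 666 and 667 without replicates 3 and 2 of 27°C with mannitol, and the highest without replicate 1 of 27°C (1765). The shared mannitol response ran from 1907 to 2896, the kept share from 0.851 to 0.902 and the warm-induced genes lowered by mannitol from 422 to 554. Genes whose sign turned in some fit were ICS1 in warmth (-0.105 to 0.12), LUX (-0.039 to 0.105), NCED3 (-0.161 to 0.073), CRA1 (-1.27 to 0.560) and RD29B (-0.065 to 1.08) in mannitol at 21°C, and IAA19 in warmth with mannitol (-0.021 to 0.199). Lists whose test turned direction in some fit, given with the same difference of means, which for several stays on one side of 0, were in mannitol at 21°C thermomorphogenesis (-0.012 to 0.045), jasmonate (-0.048 to 0.0032), carbon starvation (-0.155 to 0.022), brassinosteroid and gibberellin (-0.034 to 0.058) and abscisic acid (0.037 to 0.20). Elsewhere they were reference genes in warmth (-0.090 to -0.046) and in mannitol at 27°C (-0.113 to -0.069), jasmonate in warmth with mannitol (0.0019 to 0.052), and seed storage (-0.093 to 0.687) and root markers (-0.381 to -0.103) in the interaction.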

Other observations

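The gene groups here were put together only after the values were seen, so their counts are descriptions. Aliphatic glucosinolate synthesis, a branch of defense metabolism in the cabbage family, was lower at 27°C, with 16 of 18 genes falling and 0 rising (median -1.05, and 18 falling with rescaling). The chain elongation enzymes BCAT4 and MAM1 fell by 1.69 ± 0.22 and 1.05 ± 0.14, and CYP83A1, of the core pathway, by 1.05 ± 0.09. MYB29, a regulator of the branch, fell by 1.32 ± 0.26; its relative MYB28 was at -0.13 (adjusted p = 0.183) and is among those falling with rescaling. Mannitol at 21°C lowered 11 of the 18 and raised 0 (median -0.43), and at 27°C 6 fell and 3 rose, or 10 and 3 with rescaling. Camalexin and related indole defense genes went the other way, with 8 of 9 higher and 0 lower with mannitol at both temperatures. CYP71A13 was listed at 0 in both groups without mannitol and at 6.21 ± 1.94 TPM with mannitol at 21°C. PAD3, the last step of camalexin synthesis, rose by 1.47 ± 0.18 at 21°C and 0.85 ± 0.18 at 27°C. Warmth alone raised 7 and lowered 1 of them, and 4 of the 9 had an interaction below 0 and 1 above.

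Cuticle genes split within the pathway under mannitol at 21°C, 8 of 21 rising and 7 falling, and 4 and 7 with rescaling. PEL3 fell by 2.50 ± 0.09, and the cutin genes HTH and CYP77A6 by 1.07 ± 0.08 and 1.14 ± 0.14, while MYB96, a regulator of wax synthesis in drought, rose by 1.43 ± 0.13 and KCS1, which elongates fatty acids, by 0.76 ± 0.07. The iron regulators of bHLH group Ib rose with warmth, 4 of 4 with a median of 2.69, BHLH38 by 2.41 ± 0.38 and BHLH100 by 3.59 ± 0.43. With mannitol at 21°C 4 of 4 rose as well (median 1.70), and with mannitol at 27°C 0 of 4 passed (median 0.10). Their interaction passed for 1 of 4, with a median of -1.63. Libraries within a group differed widely for these 4 genes. All 4 climbed from replicate 1 to replicate 3 of 21°C, BHLH100 at 2.57, 6.15 and 13.3 TPM. At 27°C all 4 were highest in replicate 2, BHLH100 at 153 TPM against 67.3 and 59.1.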
